A study of Drosophila melanogaster with 17 samples.

How the data were processed

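The 17 samples were poly-A RNA libraries (PicoPure extraction and TruSeq version 2 preparation, per the labels) of fat body, midgut and whole gut. The deposited files hold raw read count values, 1 per annotated gene, with gene symbol, chromosome, start, end and strand. Per the submitters' processing notes, bases were called with CASAVA 1.8 and reads were aligned with TopHat2, and edgeR is named as a later tool. The counting tool, the strand setting, the treatment of reads that map to several places and the genome build are not stated. Chromosome names are in the style of release 5, and a release 6 annotation was used for names and synonyms alone (13837 loci matched). Because the strand of counting and the treatment of exons are unknown, values of genes that share positions with another gene, by a few bases or in full, are uncertain. Among the genes given a value these are AGO2, Acsl, AttB, Cpr47Ea, Cyp4g1, Cyp4p2, Cyp6a2, Dcr-2, Def, E(z), GstD9, Hml, Hsp22, Irk3, LamC, Msp-300, Nup107, Nup154, PGRP-LB, Rel, RpL24-like, RpS20, RpS29, TotX, baf, betaTry, fit, klar, proPO-A1, tobi, vas and y.

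Each file had 15080 entries. Entries at the same position with equal counts in all samples were merged to 14095 loci, and 29 positions whose counts were unequal were left apart. At least 1 library had a count at 13661 loci. Symbols found at several places (221 loci) hold at most 0.028% of the reads. The total counts are given per library in the report, and the detected genes as a range over the libraries. At these depths 3 counts, the most that a gene with 0 reads may hold at 95% confidence, are 0.038 to 0.095 CPM.

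Samples were grouped by tissue and by age or RNAi as labelled. The labels do not say whether replicates come from separate flies, although the series design text calls them biological replicates, so p-values measure only the spread between these samples, and intervals of single counts and floors cover counting error alone. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg adjusted p below 0.05), with 1 fit per tissue for comparisons within it and 1 fit of all 17 samples for differences between tissues. The fits held 10866 genes in fat body, 10220 in midgut, 9773 in whole gut and 11128 in all, with 4, 3, 2 and 9 residual degrees of freedom and biological coefficients of variation of 19.4, 6.6, 7.3 and 13.9%. Standard errors were taken as the fold change over the square root of F. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

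The 30 gene lists (512 entries, 3 of them unmatched and 45 matched through a synonym) covered immune, stress, growth, digestive, metabolic and nuclear processes and marker genes of other tissues. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and again with an estimated correlation, with fry and with replicate number as a block. The smallest list tested had 3 members. For each comparison with young samples the named genes are Lam, the 8 largest rises and 8 largest falls among genes that passed with a mean log2 CPM of at least 3, groups that do not overlap and a symbol that is not a computed identifier, and up to 4 members of each list with the smallest p, with any lamina member that passed. A gene named for 1 comparison may have its values given in others.

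The lists, the tests, the thresholds and most alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0 size factors and upper quartile factors in edgeR, other count filters (none, or at least 1 CPM in 2 samples), DESeq2, limma-voom, replicate number as a block, all 17 samples or only the compared groups in the fit, an adjusted p below 0.01, a 2-fold minimum, and each replicate left out in turn. Alternatives added after the data were seen were scaling by total counts alone, old fat body replicates 1 and 3 left out, genes high in fat body left out (at least 4 times the level of the old and Lam-RNAi midgut libraries), and a block with the midgut numbers crossed. Deviations of samples with the same number correlated between -0.205 and -0.006 across genes, so the numbers do not pair the samples and no block was used. Within groups no libraries were copies of each other, since replicate pairs differed by a chi-square per gene of 7.73 to 336.

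The tests were checked on simulated data with 200 changed genes in each comparison, where the proteasome list was raised as well. At 2-fold and 4-fold they recovered 60.2 and 85.6% in old against young fat body, 46.5 and 83.5% in Lam-RNAi fat body, 54 and 83.7% in old against Lam-RNAi fat body, 90.8 and 93.9% in old midgut, 91.9 and 97% in Lam-RNAi midgut, 91.9 and 99% in old against Lam-RNAi midgut, and 81.4 and 97% in whole gut. For the differences between tissues these were 58 and 83% (age, fat body and midgut), 46.5 and 81.8% (Lam RNAi) and 56.6 and 78% (age, midgut and whole gut). Between 0.04 and 0.3% of unchanged genes were called. In the data 35.7 to 55.4% of genes were called in the comparisons with young samples, far more than were changed in the simulations. The simulated rates of recovery and false calls therefore need not hold for the data. Overlaps of calls were set against 20 simulations with shared young libraries and no true change. Splicing, sequence variants and protein levels were not analysed here.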

Results

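Poly-A RNA from dissected tissues of adult Drosophila melanogaster was sequenced and counted per annotated gene. The series held 17 libraries in 8 groups. Fat body, the organ that stores fat and glycogen and secretes yolk and immune proteins, was sampled at 5 days of age (2 libraries), at 50 days (3 libraries) and at 5 days in flies with RNA interference against Lam (2 libraries). Midgut, the absorptive and enzyme-secreting part of the intestine, was sampled at 5 days, at 50 days and at 5 days with the same interference (2 libraries each). A separate series of whole guts compared 5 days with 40 days (2 libraries each). Lam encodes lamin-B, a filament protein of the nuclear lamina that lies under the inner nuclear membrane. The groups ask how each tissue changes with age, how it changes when Lam is targeted in young flies, and whether these changes are alike. The labels do not give the sex of the flies, the driver line or the tissue in which the interference was expressed.

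Sequencing depth, as total counted reads, was 33380338 and 56384135 in young fat body, 46290343, 37767677 and 45280647 in old fat body and 46640212 and 68446021 in Lam-RNAi fat body. The totals were 34162931 and 36216068 in young midgut, 32022342 and 78289614 in old midgut and 50996316 and 60154934 in Lam-RNAi midgut. In whole gut they were 33735097 and 31637135 at 5 days and 36572942 and 34054579 at 40 days. Each library detected between 10383 and 12670 genes with at least 1 read, and a gene with no read may hold up to 0.038 to 0.095 CPM (counts scaled by the library total), the level that 3 counts give at these depths. Levels below are CPM of the total count, as mean ± SD over the libraries of a group. Fold changes are corrected for library composition, so they can differ from the ratio of CPM.

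Lam (2L, 5542527 to 5546642, plus strand) fell in fat body with Lam RNAi and did not pass with age in any of the 3 tissue series. In Lam-RNAi fat body its level was 15.8 ± 0.383 CPM, against 38.7 ± 0.412 CPM in young fat body, and the log2 fold change was -1.12 (SE 0.14, 95% interval -1.5 to -0.74, adjusted p = 0.00145), a level 2.17-fold lower. The 3 old fat body libraries held 41.2, 50.8 and 42.0 CPM, and the change with age was 0.12 (-0.22 to 0.47, adjusted p = 0.464). It became 0.35 (adjusted p = 0.00599) with old fat body replicates 1 and 3 left out. In midgut Lam did not pass with age (0.02, -0.19 to 0.23, adjusted p = 0.794) or with Lam RNAi (-0.11, -0.32 to 0.1, adjusted p = 0.173), and both intervals exclude a fall of 2-fold. The effect of the interference was stronger in fat body than in midgut by -1.06 (-1.43 to -0.68, adjusted p = 0.000194). In whole gut the levels were 18.1 ± 1.97 CPM at 5 days and 29.6 ± 1.69 CPM at 40 days, and the change of 0.21 (-0.27 to 0.69) did not pass (adjusted p = 0.152). That result passed without young whole gut replicate 1 (0.33, adjusted p = 0.00354), with upper quartile scaling (0.32, adjusted p = 0.0333) and with scaling by total counts alone (0.71, adjusted p = 9.91e-05). The reads measure transcript, so protein level was not measured here.

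**Figure D1:**
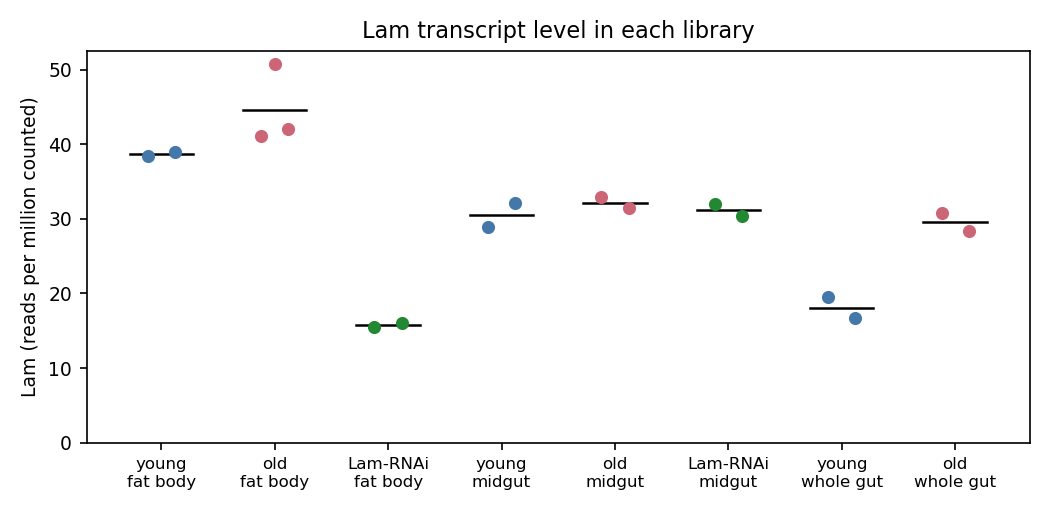
Lam transcript level in each library, in CPM (linear axis from 0), with 1 point per library and a line at the mean of each group. The Lam-RNAi fat body libraries lie at 15.5 and 16.1 CPM, under the young fat body libraries at 38.4 and 39.0 CPM, while the 6 midgut libraries lie between 28.9 and 32.9 CPM.

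Old against young fat body asks what changes in this organ between 5 and 50 days (n = 3 and 2). The largest rises were in immune genes, with antimicrobial peptide transcripts going from 104 CPM in sum to 23820 CPM. Genes of the IMD, Toll and JAK-STAT pathways, through which flies sense microbes and stress, rose with them. More detoxification enzyme genes rose (19) than fell (6), and 15 of 20 muscle, 3 of 5 oenocyte and 5 of 6 tracheal markers fell. With an estimated correlation between genes none of the 30 lists passed (lowest adjusted p = 0.178). Of 10866 genes tested, 4141 changed, 2080 higher and 2061 lower, and 1176 rose and 649 fell by at least 2-fold. The count was 2083 without young replicate 1, 1960 without young replicate 2 and 2558 without old replicate 3, a library that lay between the other old libraries in gene after gene.

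Antimicrobial peptides are small secreted proteins that kill bacteria and fungi in the blood of the fly. In old fat body 18 of the 19 tested rose and 1 did not pass, against 19 that rose adjusted over the list alone. The median log2 fold change was 8.26 with genes near 0 reads held at their bound, and the list stood apart from other genes (camera adjusted p = 1.44e-23, and adjusted p = 0.178 with an estimated correlation). CecA2 (3R, 26037878 to 26038291) went from 0.185 ± 0.0354 to 148 ± 24.5 CPM (log2 fold change 9.58, SE 0.23, adjusted p = 1.15e-05), a 766-fold rise. Dpt (2R, 14753270 to 14753765) went from 9.68 ± 0.935 to 5015 ± 600 CPM (8.93, SE 0.27, adjusted p = 1.63e-05). Drs, the antifungal peptide under Toll control, rose from 15.6 ± 1.62 to 2613 ± 273 CPM. The other large rises among named genes were CecA1 (763-fold), AttD (646-fold), AttA (633-fold), AttB (423-fold), the locus of IM18/CG10332, 2 entries at 1 position (395-fold) and tobi, a glucosidase gene under insulin and glucagon-like control (384-fold; it overlaps rha by 78 bases, so its value is uncertain).

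**Figure D2:**
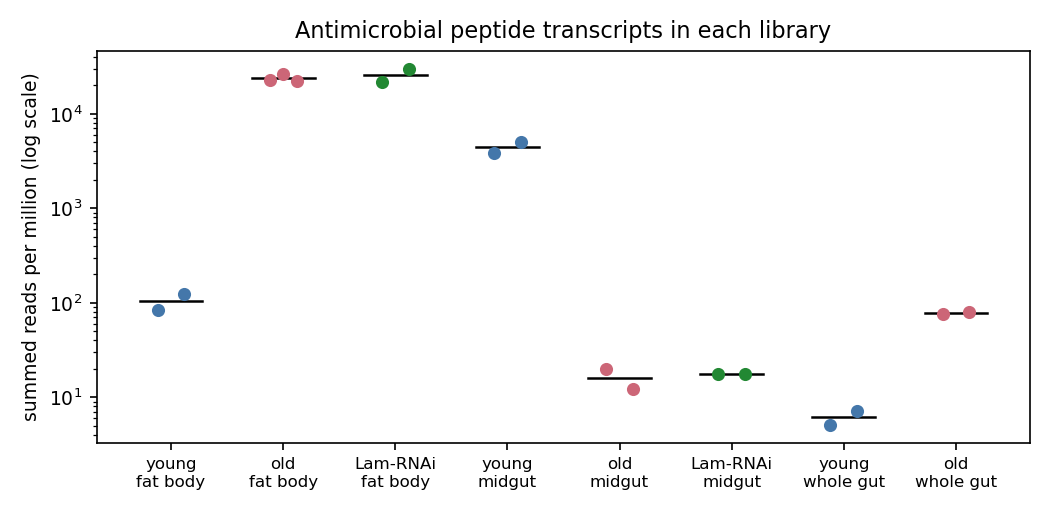
Summed transcript level of the antimicrobial peptide genes in each library, in CPM on a log scale, with 1 point per library and a line at each group mean. Means were 104 CPM in young fat body, 23820 CPM in old and 25930 CPM in Lam-RNAi fat body, 4424 CPM in young midgut, 16.1 CPM in old and 17.6 CPM in Lam-RNAi midgut, and 6.12 and 77.4 CPM in young and old whole gut.

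The IMD pathway, which detects bacterial peptidoglycan, had 16 members that rose, 0 that fell and 7 that did not pass (18 rose adjusted over the list alone; camera adjusted p = 4.2e-10, and adjusted p = 0.242 with an estimated correlation). Its transcription factor Rel rose from 266 ± 3.34 to 1081 ± 14.0 CPM. Genes whose proteins damp the pathway rose further, PGRP-SC2 by 298-fold and pirk by 36.6-fold. The Toll pathway with the Bomanin peptides had 14 that rose, 3 that fell and 6 that did not pass (14 and 4 adjusted over the list alone, 15 and 5 without old replicate 1; camera adjusted p = 0.000113, and adjusted p = 0.415 with an estimated correlation). There the protease gene psh rose from 74.2 ± 4.35 to 926 ± 117 CPM and IM3 from 174 ± 0.216 to 1507 ± 152 CPM. In the JAK-STAT list 9 rose, 1 fell and 4 did not pass (11 and 1 adjusted over the list alone; camera adjusted p = 0.00249, and adjusted p = 0.354 with an estimated correlation). The stress peptide genes TotM (124-fold) and TotX (5.00-fold) rose, while CG14225, a receptor-like gene of this list, fell from 111 ± 3.79 to 27.0 ± 3.90 CPM.

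Glutathione transferases, P450s and redox enzymes, which clear toxins and oxidants, had 19 that rose, 6 that fell and 10 that did not pass (20 and 7 adjusted over the list alone; camera adjusted p = 0.00452, and adjusted p = 0.354 with an estimated correlation). Cyp6w1 rose from 110 ± 3.59 to 502 ± 14.8 CPM and GstE7 by 8.89-fold, while Sod fell by 1.01 on the log2 scale. Without young replicate 1 the list had 10 that rose and 2 that fell, without young replicate 2 it had 6 and 4, and without old replicate 3 it had 14 and 3. Digestive enzyme genes had 13 that rose, 3 that fell and 18 that did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 0.0131, and adjusted p = 0.66 with an estimated correlation). Their summed level was 264 ± 2.83 CPM in young and 1006 ± 679 CPM in old fat body, against 109100 CPM in young midgut. The number that rose was 7 without young replicate 1, 5 without young replicate 2 and 8 without old replicate 1. Among them betaTry, a trypsin gene, rose from 4.93 ± 0.450 to 21.3 ± 2.0 CPM. The peritrophic matrix and septate junction list had 5 that rose, 1 that fell and 7 that did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.0271, and adjusted p = 0.354 with an estimated correlation), and its Peritrophin-15a rose 126-fold to 10.8 ± 1.37 CPM. The rises in that list numbered 2 without either young library, 3 without old replicate 3 and 8 without old replicate 2.

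Of the oxidative phosphorylation genes 0 rose, 13 fell and 16 did not pass (0 and 16 adjusted over the list alone; median -0.47; camera adjusted p = 0.000422, and adjusted p = 0.699 with an estimated correlation). Proteasome subunits, which degrade tagged proteins, had 12 that rose, 0 that fell and 17 that did not pass (14 rose adjusted over the list alone; median 0.36; camera adjusted p = 0.00249, and adjusted p = 0.699 with an estimated correlation). The calls varied with the library left out: the 13 became 1, 0 and 3 and the 12 became 1, 1 and 3 without young replicate 1, young replicate 2 and old replicate 3, and 25 and 22 without old replicate 2. The endoplasmic reticulum chaperone Hsc70-3 fell from 3646 ± 61.4 to 799 ± 16.4 CPM, within a heat shock list of 1 that rose, 5 that fell and 11 that did not pass (8 fell without old replicate 1). The lipid list had 7 that rose, 4 that fell and 8 that did not pass (4 and 2 without either young library). In it Acsl, an acyl-CoA synthetase gene, fell from 4040 ± 51.1 to 1193 ± 91.2 CPM and the lipase gene Lip4 rose from 78.9 ± 1.66 to 204 ± 35.1 CPM. Fat body secreted and storage proteins had 6 that rose, 1 that fell and 9 that did not pass, with a median of -0.04, a mean of 0.24 and 3 that rose and 6 that fell without young replicate 2. The iron carrier gene Tsf1 rose 9.27-fold in that list.

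Nuclear lamina and envelope genes had 1 that rose, 2 that fell and 13 that did not pass, and the inner membrane protein gene MAN1 fell from 62.3 ± 2.10 to 35.4 ± 2.78 CPM. Also called were koi (log2 fold change -0.62), which lost its call without young replicate 2 (-0.51), and baf (0.75), which lost it without either young library (0.83 and 0.68) or old replicate 3 (0.77). Heterochromatin and silencing factors had 2 that rose, 3 that fell and 17 that did not pass, with 5 and 2 by total counts alone, 4 and 4 without old replicate 1 and at most 1 of each without either young library or old replicate 3, and the small-RNA enzyme gene Dcr-2 fell by 0.78 on the log2 scale. Among growth and signalling lists, EGFR ligands and targets had 4 that rose and 1 that fell of 9, JNK genes 5 and 1 of 12, insulin and nutrient signalling 5 and 3 of 16, and cell cycle genes 8 and 3 of 33. The EGFR rises were 1 without young replicate 1, the JNK rises 3 and the insulin rises 2 without either young library, and the insulin rises 3 without old replicate 3. In the JNK list puc, a phosphatase gene induced by the pathway, rose from 45.2 ± 3.92 to 134 ± 36.5 CPM. The cell cycle count of 8 became 1 and 3 without young replicates 1 and 2, 2 without old replicate 3 and 15 without old replicate 1.

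Transcripts typical of other cell types moved in the same libraries. Muscle markers had 2 that rose, 15 that fell and 3 that did not pass (2 and 16 adjusted over the list alone; camera adjusted p = 4.21e-05, and adjusted p = 0.521 with an estimated correlation), and 9 fell without either young library. Act79B fell from 119 ± 7.78 to 27.8 ± 1.51 CPM. Oenocytes are wax-making cells, and of their 5 markers 3 fell (camera adjusted p = 0.0181, and adjusted p = 0.354 with an estimated correlation). Cyp4g1 went from 90110 ± 788 to 28960 ± 6264 CPM and the elongase gene eloF from 2812 ± 39.0 to 460 ± 190 CPM. Tracheal markers had 5 of 6 that fell (camera adjusted p = 0.000254, and adjusted p = 0.354 with an estimated correlation), and serp fell from 183 ± 5.28 to 69.5 ± 1.17 CPM. Ovary and eggshell markers had 5 of 10 that rose (6 adjusted over the list alone; camera adjusted p = 0.00178, and adjusted p = 0.354 with an estimated correlation), with vas going from 3.21 ± 0.422 to 11.8 ± 2.81 CPM. Hindgut markers had 4 of 5 that rose, or 2 without either young library (5 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.354 with an estimated correlation). The 3 male markers tested had 2 that rose and 1 that fell, and roX1, a dosage-compensation RNA, rose from 1.31 ± 0.223 to 7.93 ± 0.445 CPM. Hemocyte markers had 2 that rose and 5 that fell of 15 (3 fell without either young library and 4 rose and 7 fell without old replicate 1), neuron markers 0 and 2 of 10, and Malpighian tubule markers 1 and 1 of 9 (3 and 2 without old replicate 1). Intestinal progenitor genes had 4 that rose and 2 that fell of 14, with a median of -0.16 and a mean of 0.61, and enteroendocrine genes 4 and 1 of 11. The progenitor rises numbered 1 without either young library or old replicate 3, the falls numbered 5 without old replicate 2, and the enteroendocrine rises 2 and 1 without young replicates 1 and 2. The steepest named fall was in Syt4 (3R, 3091783 to 3096533), a vesicle-fusion gene, from 58.6 ± 2.41 to 2.66 ± 0.401 CPM (log2 fold change -4.55, adjusted p = 1.79e-05). Behind it came Cyp4p2 (13.9-fold lower), Scp2 (9.77-fold), the cuticle gene Cpr47Ea (9.26-fold) and Ugt35b (6.60-fold).

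Lam-RNAi against young fat body asks what follows when Lam is targeted in flies of the same young age (n = 2 and 2). The 18 antimicrobial peptide genes that rose in old fat body rose here too, to a sum of 25930 CPM (SD 5883) against 23820 CPM (SD 2093) in old flies. Members of the Toll and IMD pathways, yolk proteins, digestive enzyme genes and 15 of 33 cell cycle genes rose as well. Among chaperones 7 of 17 fell. With an estimated correlation none of the 30 lists passed (lowest adjusted p = 0.22). Of 10866 genes, 3875 changed, 2015 higher and 1860 lower, and 1140 rose and 551 fell by at least 2-fold. The count was 2057 and 1961 without young replicates 1 and 2, 1924 and 1824 without Lam-RNAi replicates 1 and 2, and 6603 when only these 4 libraries were fitted. Scaling by total counts alone lowered all changes by a median of 0.17 on the log2 scale, and 34.9% of the calls were then higher, against 52%.

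Antimicrobial peptides had 18 that rose and 1 that did not pass (18 rose adjusted over the list alone), with a median of 8.24 (camera adjusted p = 3.88e-27, and adjusted p = 0.22 with an estimated correlation). CecA1 went from 0.297 to 454 ± 137 CPM (log2 fold change 10.61, SE 0.45, adjusted p = 3.42e-05), a 1558-fold rise, and Dpt went from 9.68 ± 0.935 to 5205 ± 1360 CPM. TepI (2L, 15888639 to 15893811), whose thioester protein binds microbes, went from 3.36 to 2663 ± 701 CPM. In the IMD list 14 rose, 0 fell and 9 did not pass (15 rose adjusted over the list alone; camera adjusted p = 8.05e-08, and adjusted p = 0.341 with an estimated correlation), with PGRP-LB going from 17.0 ± 0.0707 to 457 ± 115 CPM. Toll genes and Bomanins had 14 that rose, 3 that fell and 6 that did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 6.77e-06, and adjusted p = 0.492 with an estimated correlation), and psh rose 35.5-fold. Of the falls 1 remained without young replicate 1 or Lam-RNAi replicate 2. For JAK-STAT 7 rose, 1 fell and 6 did not pass (camera adjusted p = 0.0498, and adjusted p = 0.562 with an estimated correlation; 0.0583 with replicate number as a block), and 3 fell by total counts alone. TotX rose from 18.1 ± 1.93 to 254 ± 54.0 CPM and TotC 16.3-fold. Adjusted over the list alone the JAK-STAT counts were 7 and 1.

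Yolk and other secreted fat body proteins had 7 that rose, 1 that fell and 8 that did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.505 with an estimated correlation). Without young replicate 1 the list had 11 that rose, and without young replicate 2 it had 6 that rose and 4 that fell. The yolk protein gene Yp1 rose from 16160 ± 208 to 52790 ± 6240 CPM, Yp3 from 11740 ± 266 to 32370 ± 3974 CPM and Tsf1 15.4-fold. Ovary and eggshell markers rose beside them, 7 of 10 (9 adjusted over the list alone; camera adjusted p = 6.14e-06, and adjusted p = 0.277 with an estimated correlation), and vas reached 21.0 ± 3.92 CPM against 3.21 ± 0.422 CPM. Cell cycle genes had 15 that rose, 0 that fell and 18 that did not pass (15 rose adjusted over the list alone; camera adjusted p = 0.000537, and adjusted p = 0.617 with an estimated correlation). Among them the replication clamp gene mus209 rose from 6.78 ± 0.853 to 15.9 ± 2.43 CPM and RnrS from 17.8 ± 1.40 to 32.2 ± 4.30 CPM. Their number was 4 without young replicate 1 or Lam-RNAi replicate 1 and 8 without young replicate 2. Digestive enzymes had 15 that rose, 0 that fell and 19 that did not pass (16 rose adjusted over the list alone; camera adjusted p = 0.000132, and adjusted p = 0.505 with an estimated correlation), or 7 without young replicate 2 or Lam-RNAi replicate 1 and 9 without Lam-RNAi replicate 2. The summed level of the digestive enzymes was 264 ± 2.83 CPM in young and 527 ± 41.2 CPM in Lam-RNAi fat body, against 103800 CPM in Lam-RNAi midgut. Among them betaTry rose 11.3-fold to 49.5 ± 12.1 CPM and Amy-d, an amylase gene, from 14.9 ± 0.0911 to 49.9 ± 6.19 CPM. Hindgut markers rose in 3 of 5 (4 adjusted over the list alone; camera adjusted p = 0.0272, and adjusted p = 0.492 with an estimated correlation).

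Heat shock proteins had 0 that rose, 7 that fell and 10 that did not pass (0 and 9 adjusted over the list alone; camera adjusted p = 0.000861, and adjusted p = 0.617 with an estimated correlation), with 3 or 4 that fell when any of the 4 libraries was left out. Hsc70-3 fell from 3646 ± 61.4 to 818 ± 8.72 CPM. Hsp22 fell by 3.72 on the log2 scale. However, all 2034 bases of this gene lie within Hsp67Bb on the same strand, so its reads cannot be assigned to either. Ribosomal proteins had 4 that rose, 17 that fell and 65 that did not pass (3 and 11 adjusted over the list alone; median -0.18; camera adjusted p = 0.00831, and adjusted p = 0.828 with an estimated correlation). RpL24-like, which entered the list by its symbol alone, fell from 149 ± 3.01 to 79.2 ± 2.88 CPM. The number that fell lay between 3 and 6 without any of the 4 libraries and was 60 with scaling by total counts alone. Proteasome subunits had 7 that rose (7 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.828 with an estimated correlation), 0 or 1 without any of the libraries and 2 by total counts alone. Oxidative phosphorylation had 2 that fell of 29 (0 adjusted over the list alone; camera adjusted p = 0.0419, and adjusted p = 0.828 with an estimated correlation), 0 without any of the libraries and 16 by total counts alone. Insulin and nutrient signalling had 4 that rose and 2 that fell of 16 (2 and 2 without any of the 4 libraries), and ImpL2, an insulin-binding protein gene, fell from 529 ± 18.4 to 99.6 ± 14.3 CPM. In the lipid list 7 rose and 2 fell of 19, with the lipase gene bmm going from 169 ± 2.71 to 350 ± 34.5 CPM.

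Besides Lam, MAN1 (62.3 ± 2.10 to 29.6 ± 1.03 CPM) and koi (26.0 ± 2.62 to 13.1 ± 0.479 CPM) fell among nuclear lamina and envelope genes. Nup98 (-0.60), kuk (0.67), klar (0.33) and Fs(2)Ket (0.28) also passed, and each lost its call when any of the 4 libraries compared was left out. That list had 3 that rose, 4 that fell and 9 that did not pass (4 and 4 adjusted over the list alone, 0 and 3 without any of the 4 libraries). Oenocyte markers had 4 of 5 that fell, with Cyp4g1 going from 90110 ± 788 to 33800 ± 2266 CPM (log2 fold change -1.24, not passing at -1.21 without Lam-RNAi replicate 1), but 0 passed without Lam-RNAi replicate 1, 1 without young replicate 2 or Lam-RNAi replicate 2 and 2 without young replicate 1. Muscle markers had 4 that rose and 7 that fell of 20 (1 fell without any of the libraries), tracheal markers 3 and 1 of 6, and hemocyte markers 4 and 2 of 15 (0 fell without any of the libraries). Detoxification genes had 12 that rose and 5 that fell of 35 (5 to 7 rose without any of the libraries, and 9 rose and 8 fell by total counts), where Cyp6w1 rose 9.94-fold and Cyp6a2 fell from 112 ± 0.555 to 6.38 ± 0.0392 CPM. Cyp4p2 (2R, 5125035 to 5127338), a P450 gene, had 1 read in the Lam-RNAi libraries against 21847 in the young ones, a level 28010 times lower by the counts (95% counting interval 5027 to 1106000). Syt4 fell 25.7-fold and the potassium channel gene Irk3 11.2-fold.

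**Figure D3:**
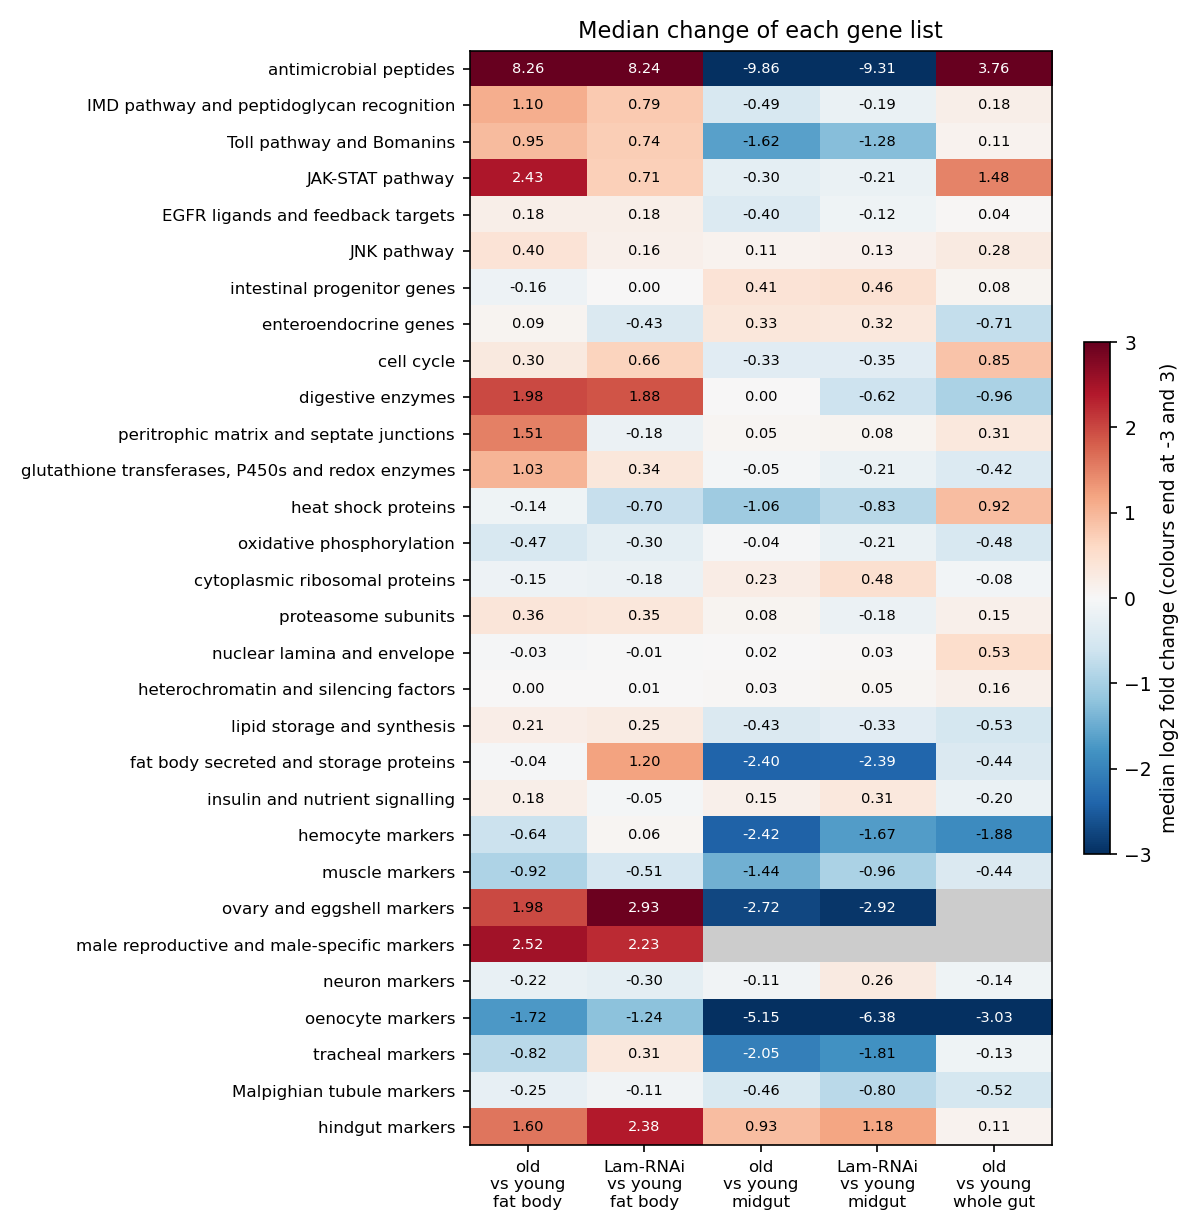
Median log2 fold change of each gene list (vertical axis) in the comparisons with young samples (horizontal axis), with genes near 0 reads held at their bound. Colours end at -3 and 3, and grey marks lists with fewer than 3 tested members. The antimicrobial peptides have medians of 8.26 and 8.24 in the fat body, -9.86 and -9.31 in the midgut and 3.76 in the whole gut.

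The age and Lam-RNAi effects in fat body overlapped widely, with 1357 genes higher in both (386 if the calls were independent), 1304 lower in both (353) and 55 in opposite directions. Both comparisons share the same young libraries, which by itself makes effects alike, and no split was made, since it would leave each comparison 1 young library, so the part of the excess that comes from sharing is not known. In 20 simulations with shared young libraries and no true change, no gene was called in both, and the correlation across genes averaged 0.551, against 0.859 observed. Without true changes hardly any gene can be called, so the lack of shared calls there does not measure what sharing adds to the overlap. The covariance was 1.886, against 0.066 simulated. Genes are not independent replicates.

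Old against Lam-RNAi fat body compares the states directly (n = 3 and 2). Of the antimicrobial peptides 0 were higher, 2 were lower and 17 did not pass, which does not show that their levels were equal. Some cell cycle, ovary, tracheal, muscle and fat body secreted genes were lower in old flies. With an estimated correlation none of the 30 lists passed (lowest adjusted p = 0.382). In all 1602 genes differed, 614 higher and 988 lower in old fat body. The count was 66 with replicate number as a block, 2531, 3542 and 479 without old replicates 1, 2 and 3, and 284 without Lam-RNAi replicate 1. Without Lam-RNAi replicate 2 it was 56 higher and 149 lower. Scaling by total counts alone raised all differences by a median of 0.26, and 81.7% of the calls were then higher. The block gives old replicate 3 a term of its own, so in effect it leaves that library out. Tracheal markers had 5 of 6 lower (camera adjusted p = 5.43e-09, and adjusted p = 0.382 with an estimated correlation), ovary and eggshell markers 5 of 10 lower (camera adjusted p = 0.000102, and adjusted p = 0.382 with an estimated correlation) and fat body secreted proteins 1 higher and 5 lower of 16 (camera adjusted p = 0.0113, and adjusted p = 0.624 with an estimated correlation). Muscle markers had 7 of 20 lower (15 adjusted over the list alone; camera adjusted p = 5.46e-07, and adjusted p = 0.624 with an estimated correlation), and cell cycle genes 7 of 33 lower (14 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.656 with an estimated correlation). Lam itself was higher in old fat body by 1.24 (0.88 to 1.6, adjusted p = 0.00274), and the call was lost with replicate number as a block (1.29, adjusted p = 0.054).

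Old against young midgut asks what changes in the intestine between 5 and 50 days (n = 2 and 2). Antimicrobial peptide transcripts moved opposite to fat body: they were abundant in young midgut and nearly absent in old midgut. Fat body secreted proteins and oenocyte, hemocyte, muscle and tracheal markers were high in the same young libraries and fell with them. Some ribosomal protein genes (41 of 85) and a few progenitor and hormone genes rose. With an estimated correlation none of the 29 lists passed (lowest adjusted p = 0.211). Of 10220 genes, 5487 changed, 2551 higher and 2936 lower, and 434 rose and 1340 fell by at least 2-fold. With genes at least 4 times higher in fat body than in the other midgut libraries left out, 4265 remained, but this filter uses the old midgut level and so removes falls more readily than rises. Upper quartile scaling put 56.5% of the calls higher, against 46%.

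Antimicrobial peptides had 0 that rose, 17 that fell and 1 that did not pass (17 fell adjusted over the list alone), with a median of -9.86 (camera adjusted p = 3.03e-38, and adjusted p = 0.211 with an estimated correlation). AttA fell from 241 ± 48.0 to 0.113 ± 0.105 CPM (log2 fold change -11.51, adjusted p = 8.13e-07), Dro 5978-fold, and Def from 119 ± 19.2 to 1.81 ± 0.0419 CPM. CecC had 1 read in old midgut against 1917 in young, 3005 times lower by the counts (538.6 to 118700). Their sum in young midgut, 4424 ± 848 CPM, exceeded that in young fat body, 104 ± 28.4 CPM. Fat body secreted proteins fell beside them, 14 of 16 with 2 that rose (14 and 2 adjusted over the list alone; camera adjusted p = 7.36e-14, and adjusted p = 0.211 with an estimated correlation), and Tsf1 went from 730 ± 129 to 44.1 ± 4.97 CPM. Oenocyte markers fell in 5 of 5 (camera adjusted p = 4.09e-13, and adjusted p = 0.211 with an estimated correlation), Cyp4g1 from 2396 ± 454 to 44.8 ± 2.45 CPM. Hemocyte markers fell in 14 of 14 (camera adjusted p = 3.15e-12, and adjusted p = 0.291 with an estimated correlation), with the matrix gene Ppn going from 245 ± 25.9 to 70.6 ± 2.81 CPM. Muscle markers fell in 19 of 20 and rose in 1 (camera adjusted p = 7.44e-16, and adjusted p = 0.29 with an estimated correlation), Act87E from 268 ± 7.92 to 48.6 ± 4.42 CPM. Tracheal markers fell in 6 of 6 (camera adjusted p = 5e-06, and adjusted p = 0.291 with an estimated correlation) and ovary markers in 6 of 9 with 1 that rose (camera adjusted p = 0.0244, and adjusted p = 0.403 with an estimated correlation; 0.0529 with replicate number as a block).

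**Figure D4:**
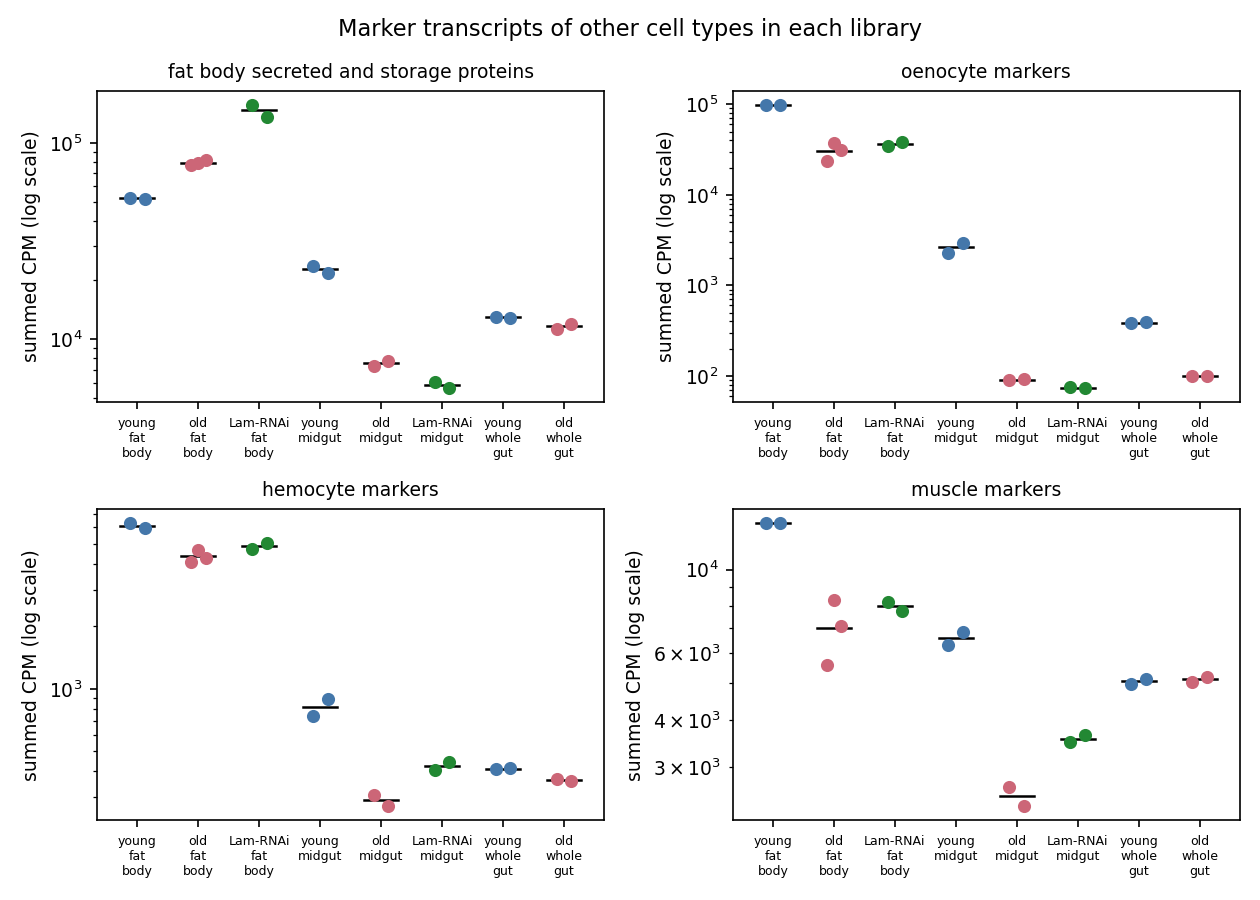
Summed transcript levels of fat body secreted, oenocyte, hemocyte and muscle marker genes in each library, in CPM on a log scale, with 1 point per library and a line at each group mean. In midgut the fat body secreted sum was 22680 CPM in the young, 7534 CPM in the old and 5874 CPM in the Lam-RNAi group, and the oenocyte sum was 2620, 91.1 and 74.4 CPM.

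Immune signalling genes fell beside the same markers. The IMD list had 3 that rose, 14 that fell and 6 that did not pass (camera adjusted p = 3.36e-07, and adjusted p = 0.211 with an estimated correlation), and pirk fell from 143 ± 11 to 21.7 ± 1.90 CPM. In the Toll list 1 rose, 19 fell and 2 did not pass (camera adjusted p = 2.09e-15, and adjusted p = 0.29 with an estimated correlation), and SPE, which activates the Toll ligand, fell 9.22-fold. For JAK-STAT 2 rose, 6 fell and 4 did not pass (camera adjusted p = 1.06e-07, and adjusted p = 0.29 with an estimated correlation), with TotA going from 346 ± 76.5 to 4.36 ± 0.775 CPM. Heat shock proteins had 2 that rose, 10 that fell and 5 that did not pass (3 and 10 adjusted over the list alone, 4 that rose without young replicate 1; camera adjusted p = 0.0212, and adjusted p = 0.626 with an estimated correlation), and Hsp26 fell from 256 ± 22.1 to 112 ± 3.80 CPM.

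Ribosomal proteins had 41 that rose, 1 that fell and 43 that did not pass (41 and 1 adjusted over the list alone; median 0.23; camera adjusted p = 0.000903, and adjusted p = 0.699 with an estimated correlation). RpS29 rose from 823 ± 62.4 to 1290 ± 9.86 CPM. The number that rose was 17 without young replicate 1, 13 without old replicate 2 and 64 with upper quartile scaling. Intestinal progenitor genes, active in stem cells and their daughters, had 8 that rose, 1 that fell and 6 that did not pass (5 rose without young replicate 2), with the stem cell factor esg going from 11.3 ± 1.29 to 23.2 ± 2.76 CPM and the Myc gene dm from 36.1 ± 4.14 to 80.5 ± 12.9 CPM. Enteroendocrine genes had 8 that rose, 3 that fell and 3 that did not pass (1 fell without young replicate 1 or either old library), and the hormone gene npf rose 2.22-fold. Neither list passed as a set (camera adjusted p = 0.0937 and 0.119). Of the cell cycle genes 3 rose, 12 fell and 18 did not pass (2 and 11 adjusted over the list alone; camera adjusted p = 0.689), and 5 fell without young replicate 2 or old replicate 1 and 6 without old replicate 2 or with another scaling. In it CycB fell from 5.90 ± 0.359 to 1.58 ± 0.342 CPM. Lamina and envelope genes had 4 that rose and 1 that fell of 16, namely Nup154 (0.45), baf (0.34), Nup107 (0.33) and LamC (0.28) upward and kuk (-0.83) downward. Digestive enzymes went both ways, 13 up and 18 down of 42 with a median of 0. The serine protease gene Jon74E (3L, 17539968 to 17542227) rose from 11.4 ± 2.26 to 1929 ± 135 CPM (log2 fold change 7.35, SE 0.15, adjusted p = 4.37e-12) while its relative Jon66Cii fell from 134 ± 7.98 to 0.411 ± 0.0511 CPM. Npc2c, a sterol-binding protein gene, rose 255-fold to 60.4 ± 7.13 CPM. Detoxification genes had 8 that rose and 17 that fell of 38, GstD9 from 342 ± 25.5 to 30.6 ± 0.644 CPM, and lipid genes 3 and 13 of 19.

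Lam-RNAi against young midgut, in flies of 5 days (n = 2 and 2), used the same young libraries, and several of the same lists fell. Lam itself did not pass there, and Lam-RNAi and old midgut differed from each other in 3678 genes. Antimicrobial peptides (17 of 18), fat body secreted proteins (14 of 16) and oenocyte (4 of 5), tracheal (6 of 6), muscle (19 of 20) and hemocyte (12 of 14) markers were again lower than in young midgut. Of 85 ribosomal protein genes 83 rose. With an estimated correlation none of the 29 lists passed (lowest adjusted p = 0.213). Of 10220 genes, 5661 changed, 2603 higher and 3058 lower, and 526 rose and 1187 fell by at least 2-fold. With genes high in fat body left out 4498 remained, by the same filter, which uses the Lam-RNAi midgut level. Scaling by upper quartiles or by total counts alone put 58.1% and 61.4% of the calls higher, against 46%, and the latter raised all changes by a median of 0.14.

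Antimicrobial peptides had 0 that rose, 17 that fell and 1 that did not pass (17 fell adjusted over the list alone; median -9.31; camera adjusted p = 1.47e-40, and adjusted p = 0.213 with an estimated correlation). AttA fell from 241 ± 48.0 to 0.101 CPM and CecC, with 1 read, was 3028 times lower by the counts (542.7 to 119600). IMD genes had 4 that rose and 13 that fell of 23 (camera adjusted p = 1.63e-05, and adjusted p = 0.302 with an estimated correlation), Toll genes 3 and 14 of 22 (3 and 15 adjusted over the list alone; camera adjusted p = 7.22e-11, and adjusted p = 0.303 with an estimated correlation) and JAK-STAT genes 2 and 6 of 12 (camera adjusted p = 2.11e-06, and adjusted p = 0.303 with an estimated correlation). PGRP-LB fell from 322 ± 28.2 to 107 ± 15 CPM and psh 24.7-fold. The markers fell in the same libraries. Fat body secreted proteins had 2 that rose and 14 that fell of 16 (camera adjusted p = 2.49e-15, and adjusted p = 0.213 with an estimated correlation). Oenocyte markers fell in 4 of 5 (camera adjusted p = 1.58e-14, and adjusted p = 0.213 with an estimated correlation), with Cyp4g1 at 21.1 ± 3.35 CPM against 2396 ± 454 CPM. Hemocyte markers fell in 12 of 14 (13 adjusted over the list alone; camera adjusted p = 1.14e-07, and adjusted p = 0.349 with an estimated correlation). Muscle markers fell in 19 of 20 (camera adjusted p = 1.24e-09, and adjusted p = 0.303 with an estimated correlation) and tracheal markers in 6 of 6 (camera adjusted p = 1.63e-05, and adjusted p = 0.303 with an estimated correlation). Ovary markers fell in 5 of 9 and rose in 2, or in 0 without Lam-RNAi replicate 2 (camera adjusted p = 0.0441, and adjusted p = 0.303 with an estimated correlation; 0.0748 with replicate number as a block).

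Ribosomal proteins had 83 that rose, 1 that fell and 1 that did not pass (83 and 1 adjusted over the list alone; median 0.48; camera adjusted p = 1.02e-09, and adjusted p = 0.559 with an estimated correlation), with RpS20 going from 538 ± 53.3 to 1010 ± 58.7 CPM. The growth regulator dm rose from 36.1 ± 4.14 to 143 ± 9.03 CPM, within a progenitor list of 7 that rose and 1 that fell of 15 (camera adjusted p = 0.0467, and adjusted p = 0.559 with an estimated correlation). Insulin and nutrient genes had 9 that rose and 3 that fell of 16 (camera adjusted p = 0.0431, and adjusted p = 0.349 with an estimated correlation; 0.0652 with replicate number as a block), among them chico, from 31.6 ± 2.77 to 60.1 ± 2.0 CPM. Proteasome subunits had 18 of 28 that fell, but 5 without young replicate 2, 8 and 3 without Lam-RNAi replicates 1 and 2, 3 by upper quartiles and 1 by total counts. Oxidative phosphorylation had 15 of 29 that fell, 9 without young replicate 2 or Lam-RNAi replicate 2, 8 by upper quartiles and 5 by total counts. Heat shock proteins had 5 that rose and 11 that fell of 17 (camera adjusted p = 0.0443, and adjusted p = 0.559 with an estimated correlation; 0.0535 with a block). Detoxification genes had 11 that rose and 18 that fell of 38 (camera adjusted p = 0.0431, and adjusted p = 0.527 with an estimated correlation; 0.07 with a block). The lamina list had 5 that rose and 3 that fell of 16. LamC, the A-type lamin gene, rose from 57.8 ± 3.06 to 91.3 ± 2.87 CPM, and Nup154 (0.44), Nup107 (0.36), Nup98 (0.24) and kuk (-0.74) passed as well, as did 3 genes that depended on single libraries. Of these baf (0.24) lost its call without young replicate 1 (0.20) or Lam-RNAi replicate 1 (0.20), klar (-0.24) without Lam-RNAi replicate 2 (-0.22) and Ote (-0.61) without any of the 4 libraries. Jon74E rose to 1736 ± 52.7 CPM, tobi from 1499 ± 158 to 8756 ± 1168 CPM and the storage protein gene Lsp1gamma 15.2-fold.

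The age and Lam-RNAi effects in midgut were called together for 1712 genes higher in both (650 if independent), 2297 lower in both (879) and 83 in opposite directions, again against the same young libraries. The correlation across genes was 0.946, against a mean of 0.566 in the simulations, which gave at most 2 genes called in both. Those simulations again held no true change, so their few shared calls do not measure what sharing adds to the overlap. Old and Lam-RNAi midgut differed in 3678 genes, 1743 higher and 1935 lower in old (n = 2 and 2), a count of 1493 without old replicate 2 and 1630 without Lam-RNAi replicate 2. Ribosomal proteins were lower in old midgut in 53 of 85 (64 adjusted over the list alone; camera adjusted p = 1.52e-07, and adjusted p = 0.842 with an estimated correlation), and proteasome subunits higher in 23 of 28 (24 adjusted over the list alone; camera adjusted p = 3.02e-06, and adjusted p = 0.842 with an estimated correlation). Antimicrobial peptides had 2 higher, 1 lower and 15 that did not pass.

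Old against young whole gut asks how the entire intestine changes by 40 days (n = 2 and 2). Of 42 digestive enzyme genes 29 fell, while 16 of 17 heat shock genes, 12 of 13 antimicrobial peptides, JAK-STAT ligands and 17 of 33 cell cycle genes rose. Respiratory-chain genes (29 of 29) and lipid genes (14 of 19) fell relative to the typical gene, while 2 and 7 fell when scaled by total counts alone. With an estimated correlation none of the 28 lists passed (lowest adjusted p = 0.239). Of 9773 genes, 4257 changed, 1969 higher and 2288 lower, and 528 rose and 564 fell by at least 2-fold. Composition factors differed between the ages, 0.835 and 0.849 in young against 1.19 and 1.186 in old libraries. Scaling by total counts alone raised all changes by a median of 0.50 and gave 6933 calls, 87.9% higher, so the changes below are relative to the typical gene. Upper quartiles raised them by 0.11.

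Digestive enzymes had 9 that rose, 29 that fell and 4 that did not pass (10 and 29 adjusted over the list alone; median -0.96; camera adjusted p = 4.95e-35, and adjusted p = 0.239 with an estimated correlation). Jon65Ai (3L, 6046684 to 6047526) fell from 2038 ± 124 to 228 ± 3.47 CPM (log2 fold change -3.66, SE 0.06, adjusted p = 2.68e-13), with Jon99Ci (12.5-fold) and Jon65Aii (9.75-fold) close to it. Antimicrobial peptides had 12 that rose and 1 that did not pass (12 rose adjusted over the list alone; median 3.76; camera adjusted p = 6.32e-06, and adjusted p = 0.239 with an estimated correlation) from a low base. Of these dro2 (3L, 3314349 to 3314682) went from 0.287 to 29.7 ± 0.325 CPM (6.16, SE 0.24, adjusted p = 2.86e-10). The IMD list had 11 that rose and 5 that fell of 23 (camera adjusted p = 0.0509), with pirk going from 37.2 ± 1.10 to 118 ± 8.34 CPM, and the Toll list 3 and 1 of 21. By total counts the IMD counts were 18 and 2 and the Toll counts 15 and 0, and without young replicates 1 and 2 the Toll falls were 3 and 4. JAK-STAT genes had 7 that rose, 0 that fell and 5 that did not pass (9 rose adjusted over the list alone; median 1.48; camera adjusted p = 6.05e-05, and adjusted p = 0.239 with an estimated correlation). The cytokine gene upd3 (X, 18171266 to 18178631), released by damaged enterocytes, went from 0.748 ± 0.0742 to 29.3 ± 1.64 CPM (4.79, SE 0.18, adjusted p = 1.85e-10) and the pathway target Socs36E from 18.9 ± 2.43 to 148 ± 12.4 CPM.

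Cell cycle genes had 17 that rose, 0 that fell and 16 that did not pass (19 rose adjusted over the list alone; camera adjusted p = 0.00357, and adjusted p = 0.253 with an estimated correlation), or 10 without either old library and 30 by total counts. RnrS rose from 14.4 ± 1.86 to 41.9 ± 1.91 CPM. Progenitor genes had 5 that rose and 2 that fell of 15, Sox21a from 3.03 ± 0.620 to 22.7 ± 0.116 CPM, and enteroendocrine genes 3 and 9 of 14, Ast-C from 70.3 ± 2.89 to 49.1 ± 1.67 CPM. JNK genes had 6 that rose and 1 that fell of 12 and EGFR genes 4 and 2 of 9 (2 rose without old replicate 2), with the protease gene rho, which frees EGFR ligands, up 3.94-fold. Heat shock proteins had 16 that rose and 1 that fell (camera adjusted p = 4.12e-13, and adjusted p = 0.239 with an estimated correlation), with Hsp83 going from 496 ± 22.2 to 2608 ± 50.3 CPM and Hsp23 5.73-fold up. Peritrophic matrix and septate junction genes had 8 that rose and 1 that fell of 14 (camera adjusted p = 3.32e-05, and adjusted p = 0.239 with an estimated correlation), and the mucin gene Mur29B rose from 179 ± 7.85 to 1073 ± 24.6 CPM. Proteasome subunits had 10 of 30 that rose (9 adjusted over the list alone), 2 without either old library, 16 without either young one and 29 by total counts. Lamina and envelope genes had 9 that rose, 1 that fell and 6 that did not pass (camera adjusted p = 0.0328, and adjusted p = 0.294 with an estimated correlation). LamC rose from 66.2 ± 3.09 to 174 ± 5.33 CPM and baf 1.72-fold. Silencing factors had 4 that rose and 3 that fell of 22 (7 and 4 without young replicate 2, 3 and 1 without old replicate 2, 18 and 0 by total counts), AGO2 from 119 ± 5.62 to 340 ± 8.21 CPM.

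Oxidative phosphorylation fell in 29 of 29 (median -0.48; camera adjusted p = 9.25e-07, and adjusted p = 0.239 with an estimated correlation), but with total counts alone 5 rose, 2 fell and the median was 0.02. Lipid genes had 3 that rose and 14 that fell of 19 (median -0.53; camera adjusted p = 3.85e-05, and adjusted p = 0.239 with an estimated correlation), with bmm going from 273 ± 15.1 to 192 ± 0.866 CPM, and 6 and 7 by total counts. Detoxification genes had 8 that rose and 23 that fell of 38 (9 and 23 adjusted over the list alone; median -0.42; camera adjusted p = 0.0139, and adjusted p = 0.323 with an estimated correlation), and 16 and 11 by total counts (median 0.08). Cyp9b2 rose there from 1045 ± 4.76 to 3968 ± 115 CPM and Gclc fell from 509 ± 3.79 to 343 ± 5.38 CPM. Ribosomal proteins had 4 that rose and 21 that fell of 84 (3 and 14 adjusted over the list alone; median -0.08), which turned to 15 and 3 by upper quartiles and 84 and 0 by total counts, and was 8 and 36 without young replicate 2, 1 and 18 without old replicate 1 and 7 and 12 without old replicate 2. Insulin genes had 6 that rose and 8 that fell of 16, with a median of -0.20, a mean of 0.70 and 9 and 0 by total counts. ImpL2 rose from 26.0 ± 3.09 to 231 ± 14.9 CPM.

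Some marker lists also had falls in whole gut, while neuron markers had 2 that rose and 0 that fell of 7, hindgut markers 1 and 0 of 4 and tracheal markers 0 and 0 of 5. Oenocyte markers had 3 of 5 that fell (camera adjusted p = 3.03e-07, and adjusted p = 0.239 with an estimated correlation), with Cyp4g1 going from 314 ± 4.84 to 46.0 ± 1.58 CPM, and hemocyte markers 9 of 11 (10 adjusted over the list alone; camera adjusted p = 3.77e-05, and adjusted p = 0.239 with an estimated correlation), with the prophenoloxidase gene proPO-A1 8.78-fold down. Fat body secreted proteins had 1 that rose and 10 that fell of 15 (camera adjusted p = 0.00261, and adjusted p = 0.239 with an estimated correlation; 4 and 6 and a median of 0.06 by total counts). Muscle markers fell in 13 of 18 (camera adjusted p = 0.00502, and adjusted p = 0.36 with an estimated correlation; 4 up, 3 down and a median of 0.05 by total counts) and Malpighian tubule markers in 7 of 9 (camera adjusted p = 0.000215, and adjusted p = 0.349 with an estimated correlation; 3 and 4 by total counts). With genes high in fat body left out, 3721 changed genes remained.

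Contrasts with young libraries differed between tissues for many genes, by tests of the difference itself. These tests pooled the spread over all 17 samples (biological coefficient of variation 13.9%), below that of fat body alone (19.4%) and above that of midgut alone (6.6%). In that fit old against young fat body gave 5503 calls in place of 4141, so the fat body spread is understated. The ageing effect differed between fat body and midgut for 4927 of 11128 genes and the Lam-RNAi effect for 5195. Antimicrobial peptides had a more positive effect of age in fat body in 19 of 19 (camera adjusted p = 3.94e-53, and 0.00102 with an estimated correlation) and of Lam RNAi in 18 of 19 (5.06e-48 and 0.00163). The IMD list did so in 17 of 24, with 1 opposite, for age (1.05e-16 and 0.0014) and in 14 with 2 opposite for Lam RNAi (3.77e-11 and 0.0106). The young midgut libraries enter these differences beside the fat body libraries, and they also held the fat body secreted (22680 against 7534 CPM in old midgut) and oenocyte (2620 against 91.1 CPM) markers at high levels. AttA differed by 20.74 (SE 0.97) for age and 20.48 for Lam RNAi on the log2 scale. The old against young effect differed between midgut (50 days) and whole gut (40 days, a separate series) for 3343 genes. It was more negative in midgut for 15 of 19 antimicrobial peptides (9.7e-29 and 0.00647) and 13 of 24 IMD genes (3.49e-10 and 0.0113).

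Age effects called in both fat body and midgut went the same way for 1106 genes and opposite ways for 1251. Of them 397 rose in both (477 if independent, odds ratio 0.748, 0.661 to 0.845) and 709 fell in both (561; odds ratio 1.55, 1.39 to 1.72). The intervals in this paragraph treat genes as independent and do not measure the spread between libraries. Overlaps with midgut also rest on the young midgut libraries. At 2-fold or more the odds ratio for rises was 2.48 (1.89 to 3.22), so its direction depends on that threshold. Midgut and whole gut shared 697 rises (505; 1.82, 1.64 to 2.03) and 905 falls (622; 2.15, 1.95 to 2.38), with 947 opposite. Fat body and whole gut shared 554 rises (360; 2.10, 1.87 to 2.36) and 545 falls (437; 1.46, 1.30 to 1.64), with 728 opposite. Lam RNAi moved 353 genes up (470; 0.643, 0.565 to 0.730) and 479 down (536; 0.827, 0.736 to 0.928) in both fat body and midgut and 1477 in opposite directions, and at 2-fold or more the odds ratios were 2.61 and 1.73.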

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

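The tests of young fat body RNA, of an age effect common to both gut series and of RNA of other tissues were chosen after the results they measure had been seen. Several effects differed between tissues by a test of the difference itself, with a spread pooled over all 17 samples that understates that of fat body. The old against young effect differed between fat body and midgut for 4927 genes. It differed between midgut (50 days) and whole gut (40 days, a separate series) for 3343 genes. The Lam-RNAi against young effect differed between fat body and midgut for 5195 genes. All of these differences, and those of the lists below, use the young midgut libraries. Those libraries also held fat body and oenocyte markers at high levels, so the tests do not show that age or Lam RNAi is the cause. The median log2 difference between fat body and midgut was 17.79 for age and 17.74 for Lam RNAi in the antimicrobial peptides, with genes near 0 reads held at their bound, and 2.06 and 1.11 in the IMD list. For Lam RNAi it was 3.57 in the fat body secreted proteins, 5.47 in the ovary and eggshell markers and 1.99 in the tracheal markers, and Lam itself differed by -1.06. Between midgut and whole gut the age difference was -12.55 in the antimicrobial peptides and -1.2 in the IMD list.

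Antimicrobial peptide transcripts were far lower in old and Lam-RNAi midgut than in young midgut. RNA of young fat body is argued against, since all 18 tested genes were higher in young midgut than in young fat body. An age effect common to both gut series is also argued against, since 12 of these genes were higher in old than in young whole gut. RNA of fat body with induced immune genes stays open. The young midgut excess was a median 17.5% of the induced fat body level for antimicrobial peptides (quartiles 15.95 and 18.95%). For secreted proteins it was 6.13%, with a wider spread (upper quartile 15.58%). The ratio was 2.847 against a bound of 3 set before the value was seen, so such RNA may be part of the cause but passed narrowly. Peptides aside, 421 genes were at least 20 times higher in fat body than in old and Lam-RNAi midgut. Their young midgut level was a median 9.41, 9.57 and 9.39% of young, old and Lam-RNAi fat body (quartiles 6.94 and 11.74% for the last). The peptide share was higher than that. A true fall of antimicrobial peptide transcripts with age and with Lam RNAi in the midgut was not tested and stays open. However, young whole gut, from a separate series, held 6.12 CPM of these peptide transcripts in sum against 4424 CPM in young midgut. That counts against such levels being usual in young gut.

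Old fat body replicate 3 lay between replicates 1 and 2. For the 150 genes at least 4-fold apart between these, its level lay a median 0.461 of the way from replicate 2 to replicate 1, with an interquartile range of 0.057 and all of them between the other libraries. Different amounts of gut tissue alone are argued against, since 81 genes at least as high in fat body as in midgut shared the fraction (interquartile range 0.06). A mixture of RNA or libraries of replicates 1 and 2 could give this pattern, and the labels do not settle it. If so, replicate 3 is not independent. Without it the count was 2558 in place of 4141 for old against young fat body and 479 in place of 1602 for old against Lam-RNAi fat body. The spread pooled over the fat body fit, used for Lam-RNAi against young as well, includes this library.

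The young midgut libraries stood apart from the other gut libraries. RNA of other tissues as the whole cause is argued against, since 109 genes were at least 4-fold higher in both old and Lam-RNAi midgut. Another stock, batch or dissection cannot be told apart from the group: 79 genes were at least 8-fold apart from all other gut libraries, against 0 for old midgut, 0 for Lam-RNAi midgut, 6 for young whole gut and 7 for old whole gut, but this count restates the pattern, and RNA of other tissues would raise it too. Age and Lam RNAi stay open, since young whole gut was nearer to young than to old midgut for 45.3% of 181 genes, between the bounds set. The interval of 37.9 to 52.9% treats genes as independent. Old whole gut was nearer to young midgut for 29.8% of these genes. Group and any such batch coincide in this design, so both midgut comparisons, their overlap and the differences between tissues that use young midgut carry this limit. In fat body a stock or batch that coincides with a group cannot be told apart either. There w, for one, lay at a mean of 0.903 CPM in young, 22.7 CPM in old and 57.2 CPM in Lam-RNAi libraries. Both fat body comparisons and their overlap, which share the young libraries, carry that limit too.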

How the results depend on the processing

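Scaling by total counts alone, old fat body replicates 1 and 3 left out, genes high in fat body left out and the crossed block were chosen after the results were seen, and the other settings before. The fat body counts moved by over 1.5 times in several settings, and the cause was not tested. With replicate number as a block the counts were 1707 (old fat body), 2036 (Lam-RNAi fat body) and 66 (old against Lam-RNAi fat body), and the Lam difference of the last was 1.29. In fat body this block gives old replicate 3 a term of its own, so in effect it leaves that library out. The crossed block gave 3784 for old against Lam-RNAi midgut.

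With a 2-fold minimum the counts were 1825, 1691 and 585 in the fat body comparisons (old, Lam-RNAi, old against Lam-RNAi), 1774, 1713 and 367 in the midgut ones, 1092 in whole gut, and 2620 (age) and 2793 (Lam RNAi) for fat body against midgut and 1772 for midgut against whole gut. Calls shared in direction were then 1109 (age and Lam RNAi, fat body), 1336 (the same, midgut), 269 (age, fat body and midgut), 248 (midgut and whole gut), 238 (fat body and whole gut) and 183 (Lam RNAi, both tissues). At an adjusted p below 0.01 they were 2183, 2037 and 503 in fat body, 2188 for old against Lam-RNAi midgut and 2079 for midgut against whole gut.

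Old against Lam-RNAi fat body gave 2566 with DESeq2, 3155 by total counts, 868 with only the compared groups and 3199 with all 17 samples, and old against Lam-RNAi midgut 1428 with all 17. Lam-RNAi fat body gave 6603 with only the compared groups and whole gut 6933 by total counts. With each library left out in turn the counts ranged over 1960 to 5198 (old fat body), 1824 to 2057 (Lam-RNAi fat body), 2.1e+02 to 3542 (old against Lam-RNAi fat body) and 1493 to 3073 (old against Lam-RNAi midgut), a lone sample being assumed to vary like the other groups. Lam in whole gut ranged over 0.09 to 0.33 and was 0.32 with upper quartiles and 0.71 by total counts. Its age effect was -0.63 for midgut against whole gut by total counts and 0.35 in fat body with old replicates 1 and 3 left out, where 5248 genes changed.

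By total counts these whole gut genes turned upward, as the shift of all genes by 0.50 brings about: dl 0.16, sty 0.10, RpL15 0.16, RpL37a 0.25, RpLP1 0.26, Msp-300 0.26, E(z) 0.04, Pepck 0.14, Gasp 0.37 and Uro 0.006. The hindgut gene byn ranged over -0.30 (without young whole gut replicate 2) to 0.41 (without young replicate 1). Of other named gene results, 63 lost their call with the block, 239 with a library left out, 45 with all 17 samples, 4 with DESeq2 and 9 with limma-voom. Of the list tests 69 lost their call with an estimated correlation, while fry lost 5 and gained 41. Depth limits genes under 0.038 to 0.095 CPM.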

Other observations

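The levels in this part were chosen after the values were seen. Pigment genes and a female-enriched gene also moved in fat body. The eye colour gene w lay at 0.689 to 1.12 CPM in young, 16.6 to 26.8 CPM in old and 50 to 64.4 CPM in Lam-RNAi fat body, and at 0.781 to 1.51 CPM in Lam-RNAi midgut. The cuticle pigment gene y lay at 0.12 to 0.408, 2.96 to 3.78 and 11.9 to 13.2 CPM in these fat body groups. The female-enriched gene fit lay at 8.32 to 8.66, 312 to 512 and 737 to 914 CPM. Their order, young below old below Lam-RNAi, held in all libraries of the 3 groups. Cyp4p2 was nearly absent in Lam-RNAi fat body but lay at 71.9 to 90.0 CPM in Lam-RNAi midgut. Whether the fat body and midgut libraries came from the same flies is not known. Sex, stock and transgene markers are not given by the labels, and no explanation of these levels was tested.

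The young fat body replicates differed in Lsp1gamma, with 187 CPM in 1 and 2.52 CPM in the other. Young midgut libraries differed from the other gut groups in single genes as well. By group mean Jon66Cii lay at 134.5 CPM in young midgut and at 0.31 to 2.05 CPM in the others and Jon74E at 11.4 CPM against 948 to 1929 CPM. By library Hml, a hemocyte gene, lay at 56.4 to 78.1 CPM in young midgut against 2.75 to 8.51 CPM in the other midgut libraries, and Cyp4g1 at 2076 to 2717 CPM against 18.8 to 46.5 CPM.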
